A study of Drosophila melanogaster with 4 samples.

How the data were processed

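Hsp90 ChIP-seq was done on 2 biological replicates of DRSC-S2 cells, with 2 input samples. Per the labels' protocols, exponentially growing cells were fixed with formaldehyde, chromatin was sonicated, and Hsp90 was precipitated with a non-commercial antibody. Library fragments were size-selected on a gel and amplified by PCR before sequencing on Illumina Genome Analyzers. Molecular identifiers are not mentioned in these protocols, so tags are not known to be independent molecules, and all intervals below cover counting error only. Reads were aligned with Bowtie to a build given as dm3 and BDGP5, per the submitters' processing notes. The versions of Bowtie and MACS and the treatment of reads that match several places are not given in the sources used here.

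Peaks were called with MACS for each replicate against its own input, per the file headers, with a p-value cutoff of 1e-05, a tag size of 38 bp, a band width of 300 bp and an effective genome size of 121 Mb. The local background was taken from the peak region and from 1, 5 and 10 kb around it. The settings were not the same for both lists: the model fold was 6 and the fragment shift d was 111 in replicate 1, against 4 and 78 in replicate 2, per the file headers. A smaller d gives narrower peaks, so lengths are compared within a list. Of 17717214 total ChIP tags in replicate 1, 24.5% were duplicates by the headers' unique tags, and of 25340075 in replicate 2, 31.3%. The inputs had 8.27% and 11.4%.

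Each peak carries values that are the authors' own. The tags column is a whole-number count of ChIP tags in the peak, deposited without normalization, so it depends on depth and peak length. The fold enrichment is a ratio of ChIP tags over the background expected from input, as the authors' peak caller gave it. The score deposited by the authors is -10 times log10 of the MACS p-value. The false discovery rate is in percent, per the file headers. Positions are in bp and are 1-based; in every peak the deposited length equals end minus start plus 1. Scores, folds and rates were used to describe and rank peaks within a list. Peak tags were summed and divided by the unique tags of the library to give the share of tags in peaks.

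No processed file of the inputs was analysed here, so input enters only through the authors' folds, scores and false discovery rates. The number of input peaks implied at a rank was computed as the rate times the rank by score.

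The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks were shared when they overlapped by at least 1 bp. Clusters of overlapping peaks holding at least 1 peak of each replicate were merged into shared regions, which took the highest score per replicate and the fold of that peak. Chance overlap came from 1000 circular shifts of replicate 2, with 1 random offset per chromosome inside the span covered by peaks. Correlations across regions had permutation p-values from 100000 resamples. Densities were taken over the span from the first to the last peak of an arm. X was compared with chromosomes 2 and 3 by permuting windows of 100 kb 100000 times. Random spacing on an arm kept the number and length of the regions. Other shares were compared by Fisher's exact test. The functions for overlap were tested on 4 simulated lists made from the 11299 peaks of replicate 1 with known shared shares. Among the lists with sharing, the share recovered after correction for chance overlap was off by at most 3.44 percentage points. The list with none shared gave a circular permutation p of 0.80. The overlaps reported below are not corrected for chance in this way.

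Before the data were examined, the tests of overlap, score agreement and chromosome arms were fixed, together with these alternatives: overlap of at least 50% of both peaks, peaks at or above the median score of their list, the 6 arms only, and each replicate alone. The rule for named regions took the 10 shared regions with the highest mean percentile of the score in the lists. Planned comparisons at transcription start sites (gene counts, gene lists and promoter motifs) were not run, since the gene table used for reference is of Release 6 and coordinates were not moved between builds. For the same reason X was compared by windows in place of genes. The tests of scaffolds, centromere-near sequence, spacing, summits and rows of unmatched peaks were chosen after the data were examined. With 2 replicates of a single condition, no test between groups was possible, and p-values describe these lists.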

Results

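Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the chaperone Hsp90 sits on chromatin in DRSC-S2 cells, a cultured Drosophila melanogaster line. The series holds 2 biological replicates of the Hsp90 immunoprecipitation and 2 of the input chromatin, which was sequenced without an antibody. The measurements analysed here are the 2 lists of Hsp90 peaks, each called by the authors against its own input. Replicate 1 rested on 13383895 unique ChIP tags against 10514709 unique input tags, and replicate 2 on 17401846 against 15814871. The title of the series names paused promoters as the targets of Hsp90. Gene start sites of the build used for the peaks were not used here, so regions are named by their dm3 coordinates and no gene is assigned to them.

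Hsp90 occupied many short sites. Replicate 1 held 11299 peaks with a median length of 804 bp (interquartile range 592 to 1173 bp), and replicate 2 held 12852 peaks with a median length of 666 bp (465 to 1012 bp). The peaks covered 11.6 Mb and 11.9 Mb. They held 27.1% of the unique ChIP tags in replicate 1 and 29.8% in replicate 2. The authors' fold enrichment over input had the same median, 4.72, in both lists, with interquartile ranges of 3.54 to 6.20 and 3.65 to 6.01. The ranges of the folds differed at the top, with a highest value of 17.84 in replicate 1 and 13.91 in replicate 2.

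The input background behind the lists differed. The false discovery rate that MACS gave had a median of 11.7% in replicate 1 and 4.37% in replicate 2. A rate under 5% was listed for 883 peaks of replicate 1 (7.81%) and 6876 of replicate 2 (53.5%). MACS derives this rate from the peaks that input shows over ChIP. Multiplied by the rank of the peak by score, the rate gave a whole number within 0.1 for 99.9% and 100% of the peaks ranked in the top 1000. These products put 49 input peaks against the 1000 best Hsp90 peaks of replicate 1 and 7 against those of replicate 2. Over the whole lists they came to 1312 and 2045 input peaks.

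The replicates placed Hsp90 at largely the same sites. Of the peaks of replicate 1, 9986 of 11299 overlapped a peak of replicate 2 by at least 1 bp, which is 88.4% (exact 95% binomial interval 87.8 to 89.0%). Of the peaks of replicate 2, 9807 of 12852 overlapped a peak of replicate 1, which is 76.3% (75.6 to 77.0%). Random circular shifts of one list along each chromosome gave means of 15.5% and 13.6%. None of the 1000 shifts reached the observed overlap, and their highest values were 20.0% and 17.3% (one-sided circular permutation p = 0.001 for both, the smallest that 1000 shifts can give). The binomial intervals cover counting error only.

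The overlap rose with the score. In the lowest 10% of scores, 58.7% of the peaks of replicate 1 and 36.2% of the peaks of replicate 2 had a partner. In the highest 10% the shares were 99.6% and 98.1%. Peaks of one replicate alone had a median fold of 2.99 in replicate 1 and 3.59 in replicate 2, against 5.04 and 5.11 for the peaks with a partner.

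**Figure D1:**
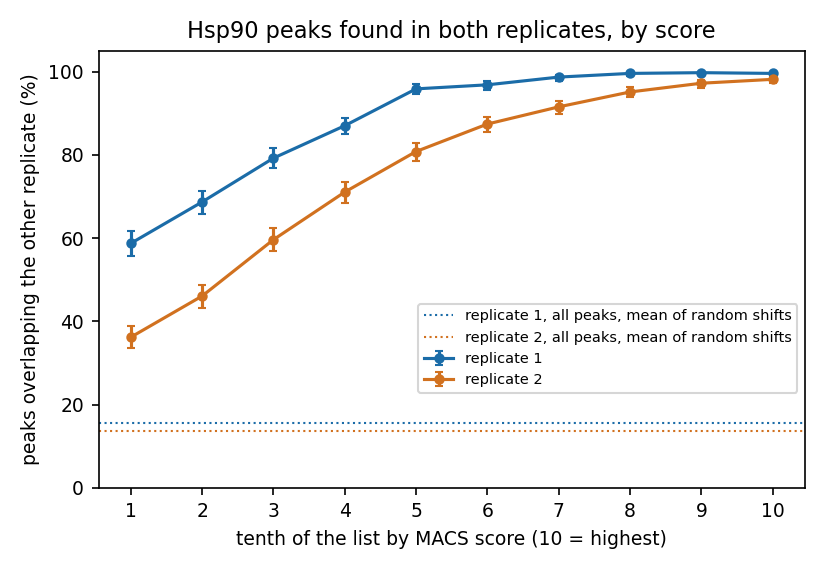
Share of Hsp90 peaks (%, y axis) that overlapped a peak of the other replicate, for the list cut by MACS score into 10 groups of like size (x axis, 10 is the highest); points are shares, bars exact 95% binomial intervals, dotted lines the mean over 1000 random shifts of all peaks. The share rose from 58.7% to 99.6% in replicate 1 and from 36.2% to 98.1% in replicate 2.

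Overlapping peaks of both replicates formed 9015 shared regions with a median length of 933 bp (interquartile range 668 to 1424 bp). They covered 11.5 Mb, and 8557 of them lay on the arms X, 2L, 2R, 3L, 3R and 4. In 7776 regions (86.3%) each replicate had a single peak. In these the summits lay a median of 22 bp apart (interquartile range 10 to 49 bp), and 84.7% were within 100 bp of each other. Across the 9015 regions the scores of the replicates correlated with a Spearman rho of 0.79 and a Pearson r of 0.83 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). The folds correlated with a rho of 0.78 and an r of 0.81 (permutation p = 1e-05 for each). These 4 correlations run across regions, which are not independent replicates, and their p-values adjusted by Benjamini-Hochberg were also 1e-05. The log2 ratio of the folds, replicate 2 over replicate 1, had a median of 0.00 and an SD of 0.32, and 99.6% of the regions differed by less than 2-fold.

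**Figure D2:**
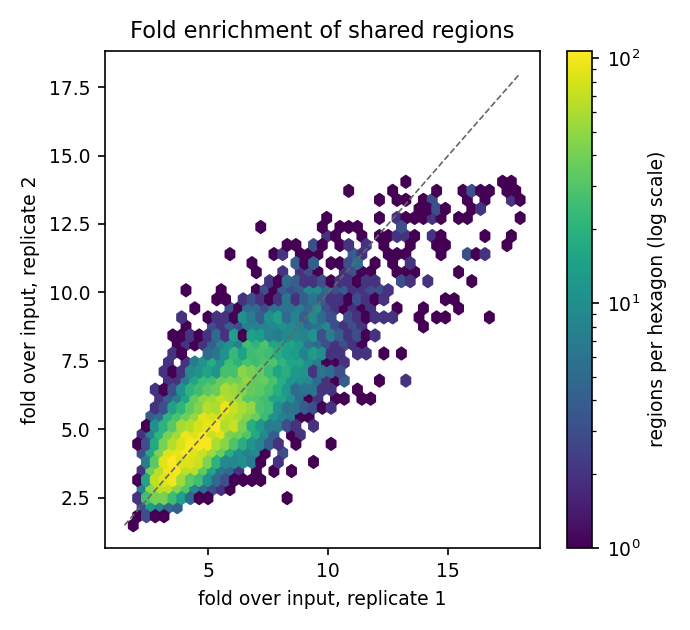
Fold enrichment over input in replicate 1 (x axis) and replicate 2 (y axis) for the 9015 shared regions; colour gives the number of regions per hexagon on a log scale and the dashed line marks equal folds. The folds followed the line (Pearson r = 0.81) up to the highest values, where those of replicate 2 ended at 13.91 and those of replicate 1 at 17.84.

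Of the 10 regions named for the highest scores in both replicates, the first 5 lay on 3R (2), 3L (2) and 2R (1). First was a 16387 bp region on 3R from 26624956 to 26641342, with a fold of 7.17 in replicate 1 and 6.66 in replicate 2. The 2189 bp region on 3R from 12059653 to 12061841 had folds of 5.92 and 4.96. The region on 3L from 537895 to 577797 had folds of 5.62 and 4.40. On 2R the region from 8883148 to 8885511 had folds of 7.86 and 6.52. The 1856 bp region on 3L from 18793029 to 18794884 had folds of 8.40 and 8.43. On 2L the region from 160313 to 162405 had folds of 6.25 and 6.21, and the one from 476562 to 508817 had 6.54 and 4.69. Also on 2L, the region from 2749178 to 2756368 had folds of 9.99 and 7.10, the one from 5976963 to 5985214 had 8.70 and 5.70, and the one from 12009861 to 12012913 had 6.98 and 5.83. The last 5 had a score of 3100 in both lists, a value shared by 31 peaks of replicate 1 and 70 of replicate 2. They were taken by position from 25 regions tied at that score, of which 5 lay on 2L, 7 on 2R, 4 on 3L, 5 on 3R and 4 on X, so neither their order nor their place on 2L is a measured one. Another tied region, on 3R from 19014623 to 19017682 and picked after its values were seen, had folds of 17.84 and 13.36. These exceed the folds of all of the first 5. A score above 3100 therefore need not mark a stronger site than a score of 3100, and the first 5 are not shown to be the strongest.

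Broad domains were few. Of the shared regions, 148 were longer than 5000 bp and 20 longer than 10000 bp. The widest spanned 39903 bp on 3L from 537895 to 577797 and held 17114 ChIP tags of replicate 1 in 6 peaks and 22176 tags of replicate 2 in 2 peaks. A 32256 bp region lay on 2L from 476562 to 508817. A further pair of neighbouring domains lay on 3L, from 3384971 to 3416313 (31343 bp) and from 3433801 to 3460989 (27189 bp). These widest regions, and the other regions named from here on, were chosen after their values were seen. One of the 10 widest, on 3R from 11838891 to 11854093, differed between the replicates: the score of its best peak was 1414 in replicate 1 and 175 in replicate 2, while its peaks held 3460 tags in replicate 1 and 8660 in replicate 2.

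Hsp90 regions stood in groups along the chromosomes. The median gap between neighbouring shared regions on the 6 arms was 3157 bp (interquartile range 541 to 10945 bp). A gap of at most 5 kb was found for 59.8% of the 8551 neighbouring pairs, against a mean of 33.0% when the same regions were spaced at random on their arm. The highest of 1000 random spacings gave 34.3% (one-sided permutation p = 0.001, the smallest they can give). Random spacing treats every region as a separate site and the whole span as open to peaks. Broad domains called as several regions, or sequence where no peak can be called, could therefore add to the difference, and their share was not tested. The densest window of 100 kb lay on X from 13139741 to 13239740 and held 37 shared regions, against a median of 6 per window. Next came windows on 3L from 17927620 to 18027619 with 30 regions, and on 2L from 12405511 to 12505510 and 3R from 12012473 to 12112472 with 29 each. At the other end, 127 of 1196 windows (10.6%) held none. The longest stretch of an arm without a shared region was on 2R from 273590 to 1105201 (832 kb), followed by X from 21245580 to 21883571 (638 kb). Not all such stretches were near a centromere: on 2L, 371 kb from 16889486 to 17260530 held no peak of either replicate.

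**Figure D3:**
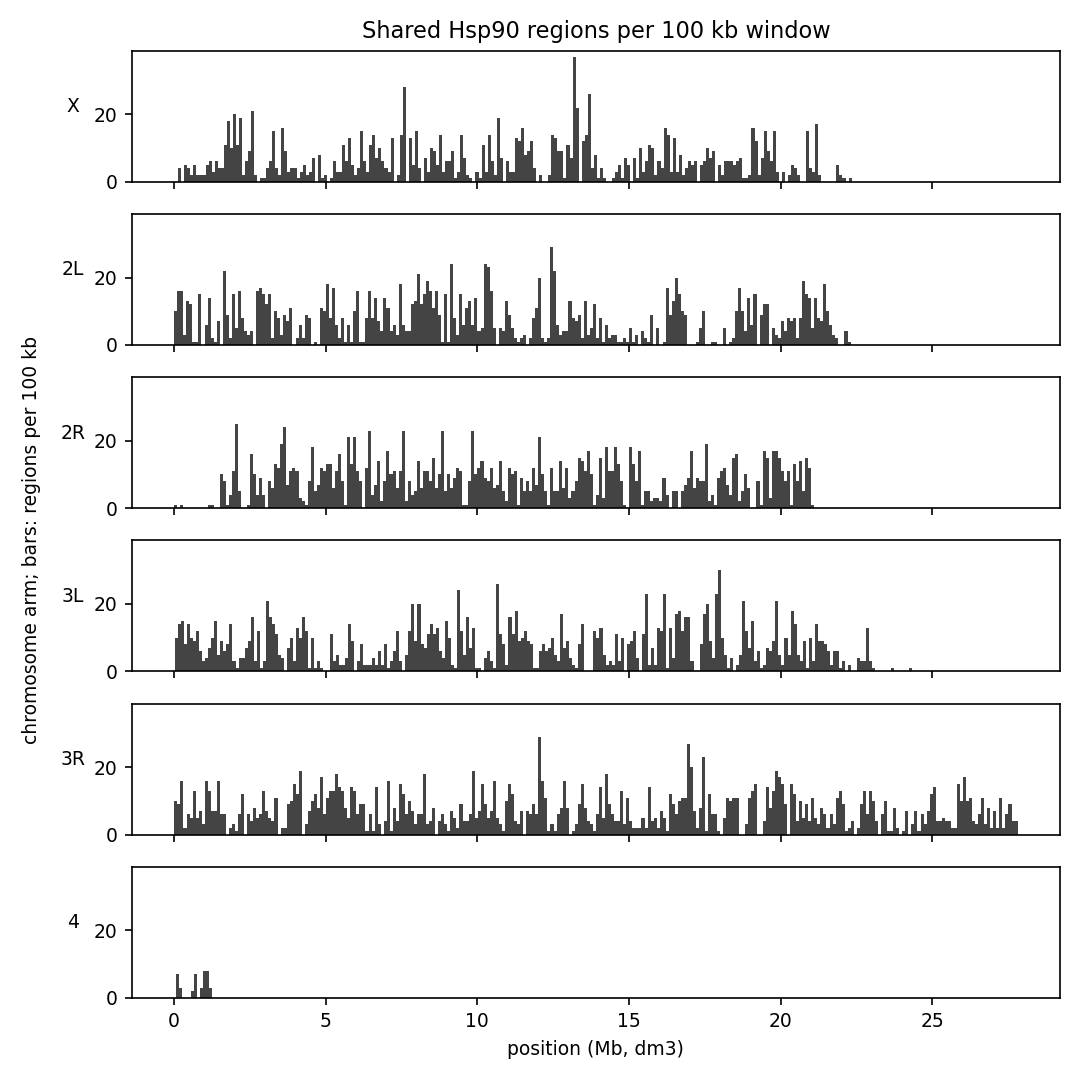
Number of shared Hsp90 regions per 100 kb window (y axis) along the 6 chromosome arms (one row each; x axis, position in Mb, dm3). The densest window, with 37 regions, is on X, and 4 of the 5 large arms thin out over the 2 Mb nearest the centromere.

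The arms differed in the density of shared Hsp90 regions. The density was highest on 2R, with 82.4 shared regions per Mb, and was 71.2 on 2L, 71.9 on 3L, 72.4 on 3R and 60.9 on X. Chromosome 4, the small and largely heterochromatic chromosome, had 37.8 per Mb, with 49 regions in all. The lists disagreed there, with 63 peaks in replicate 1 and 125 in replicate 2. The low density of shared regions on chromosome 4 is therefore not shown by each list. In windows of 100 kb, X held 61.1 ± 58.1 regions per Mb (SD, n = 222 windows) and chromosomes 2 and 3 held 74.2 ± 58.8 (SD, n = 962 windows), a ratio of 0.82 (two-sided permutation test of the windows, p = 0.00266, 100000 resamples). Neighbouring windows are not independent. In windows of 500 kb, a setting not fixed beforehand, the ratio was 0.83 (permutation p = 0.0225). The call depended on the list used: with the peaks of replicate 2 alone the ratio was 0.90 (permutation p = 0.0651), and with those of replicate 1 alone 0.80 (permutation p = 0.00131). Both ratios went the same way, and the difference between them was not tested. Peaks on X were also shorter, with medians of 683 bp against 841 bp in replicate 1 and 550 bp against 713 bp in replicate 2. Their folds were not lower, with medians of 4.97 against 4.76 in replicate 1 and 4.91 in both classes in replicate 2.

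In the 2 Mb nearest the centromere, 4 of the 5 large arms had fewer shared regions than over the rest of the arm. The density there was 15.5 per Mb on 3L against 76.9 elsewhere, 19.0 on 2R against 89.0, 28 on X against 64.2 and 39.0 on 2L against 74.3. On 3R it was 76.0 against 72.2. Over the 5 arms the means were 35.5 ± 24.4 and 75.3 ± 9.03 per Mb (SD, n = 5 arms). An exact two-sided sign-flip permutation test over n = 5 arms gave p = 0.125, in a design whose smallest p is 0.0625.

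The replicates parted most on sequence outside the large arms. On the scaffolds that hold unplaced and heterochromatic sequence lay 550 peaks of replicate 1 (4.87%, exact 95% interval 4.48 to 5.28%) and 1540 of replicate 2 (11.98%, 11.4 to 12.6%). The odds ratio was 2.66 (Fisher's exact test, two-sided, p = 2.26e-89), a test that compares these 2 libraries. Most of them were on Uextra, with 452 and 1268 peaks. Of the scaffold peaks of replicate 2, 69.9% had no partner in replicate 1 (67.6 to 72.2%), against 16.4% (15.7 to 17.1%) over the large arms away from the centromere. The share without a partner was 60.8% on chromosome 4 (76 of 125 peaks) and 27.1% in the 2 Mb nearest the centromeres (142 of 524). Each of these exceeded that of the rest of the large arms (Fisher's exact test, Benjamini-Hochberg over 6 tests, adjusted p = 4.89e-28 and 3.43e-09). In replicate 1 the peaks without a partner made up 22.2% on chromosome 4 (adjusted p = 0.0182, Fisher's exact test), 16.4% on the scaffolds (adjusted p = 0.00124) and 11.5% over the rest of the large arms. In the 2 Mb nearest the centromeres the share was lower, at 7.90% (adjusted p = 0.0212, Fisher's exact test). All these tests count each peak as independent. Unmatched peaks of replicate 2 stood in rows, of up to 22 on chromosome 4 and 148 on the scaffolds, so the p-values may be much too small.

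Some unmatched peaks stood side by side. In replicate 1, 6 peaks in a row on 3R from 25585227 to 25626993 had no partner, among them a 21115 bp peak with 14952 tags and a fold of 4.01. On X from 12612292 to 12639080, 8 peaks of replicate 1 in a row had none, with folds of 2.74 to 6.68. In replicate 2 the longest row on the 6 arms was on chromosome 4 from 203067 to 577412, where 22 peaks had no partner and folds ran from 2.67 to 9.72. Another 18 stood on X from 21246514 to 21875694, inside the centromere-near stretch that has no shared region. On the scaffolds the rows of replicate 2 were longer, with up to 148 peaks. Unplaced sequence has no known position on a chromosome, so neighbours there need not lie side by side in the genome.

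**Figure D4:**
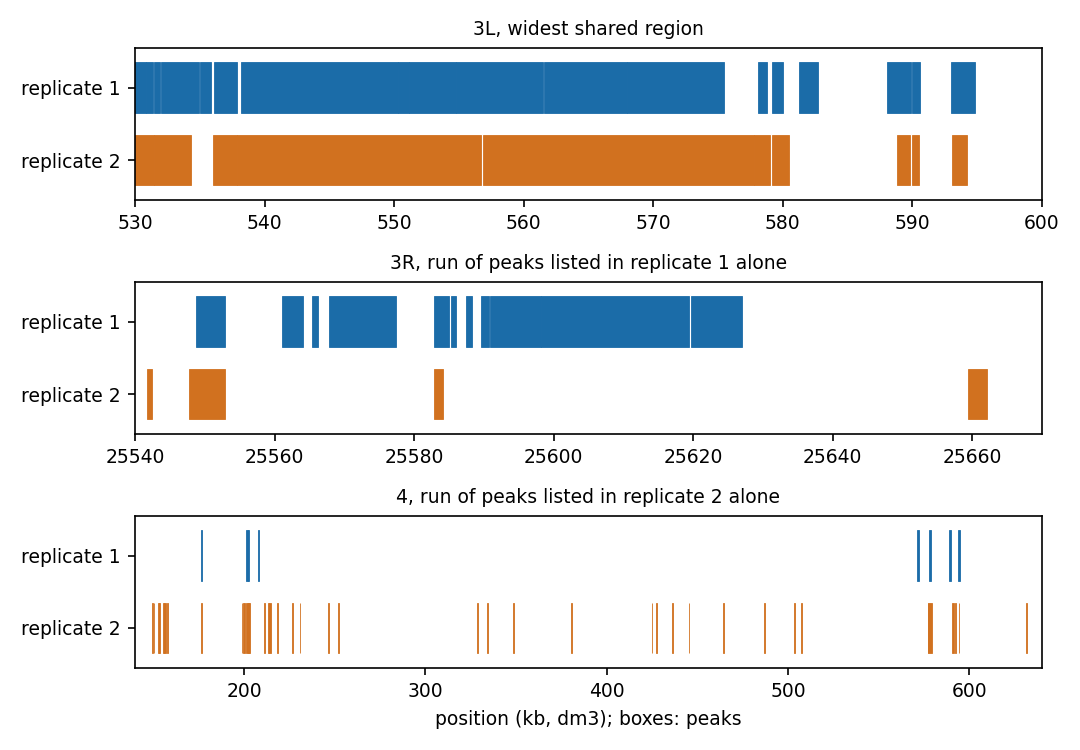
Peaks of both replicates (boxes, 1 row per replicate; x axis, position in kb, dm3) at 3 places. Top, the widest shared region, on 3L from 537895 to 577797; middle, the 3R stretch from 25585227 to 25626993 with 6 peaks of replicate 1 alone; bottom, the stretch of chromosome 4 from 203067 to 577412 with 22 peaks of replicate 2 without a partner.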

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

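The tests of repeated sequences, of the order of unmatched peaks, of depth for the rows in replicate 1, of the 3R row alone and of the fold ceiling, and the grouping of the rows by arm, were chosen after the results were seen.

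Sequence outside the comparisons of the chromosome arms also carried peaks. On the mitochondrial genome replicate 2 listed 4 peaks with folds over input of 2.08 to 3.95, and replicate 1 listed none. On YHet, heterochromatic sequence of the Y chromosome, replicate 2 listed 4 peaks with folds of 2.19 to 4.45, and replicate 1 listed none. The YHet peaks are among the scaffold peaks counted above. Their scores of 51.04 to 91.98 were near the lowest score of the list, 50.01.

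The peaks of replicate 2 that replicate 1 lacks were more often on scaffolds. Greater depth in replicate 2 would add weak peaks, yet among the 5000 highest-scoring peaks of each list the scaffold share was still 5.34% against 2.98%. The exact 95% interval of replicate 2 started at 4.73%, above the 3.49% where that of replicate 1 ended. That is the outcome named beforehand as going against depth as the whole cause. These intervals count each peak as independent, while 622 scaffold peaks of replicate 2 stood in rows of 5 or more unmatched peaks. They are therefore too narrow to exclude depth. Of the 83 unmatched peaks in the top 25% of scores, of which 63 lay on the arms and so say little about the scaffolds, 37 had a twin of the same length and tag count within 2% elsewhere, against at most 29 in 1000 sets of shared peaks matched on length, but this likeness prompted the test and the sets had higher folds (medians of 5.18 to 6.54 against 3.66), so reads shared between copies of a repeated sequence stay open for them. Over all 3045 unmatched peaks, 2617 had a twin against at most 2528 in jittered sets, but the 9807 matched peaks exceeded their jittered sets as well (9318 against at most 9295), so for these the question stays open. Off the arms, 667 of 1081 unmatched peaks had a twin, against at most 629 in jittered sets. These 1081 peaks were 1077 on the scaffolds and 4 on the mitochondrial genome. Of the 463 matched peaks there, all on scaffolds, 193 had a twin, against at most 217. That is what shared reads would give. But the unmatched count was known before the control was chosen, and the control is smaller and holds no mitochondrial peak. The question therefore stays open here too, as does an actual difference in occupancy of repeats between the cultures.

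Rows of neighbouring peaks in replicate 1 alone were the second pattern. The longest, with 8 peaks on X, exceeded the longest of 1000 sets in which matched and unmatched peaks of an arm and like score were exchanged, which was 7, and the 5 rows of 5 or more peaks exceeded the highest number in such sets, which was 3, so a chance order is unlikely for that row and for the rows as a set, while it stays open for each of the other 4 taken alone. Depth argues the other way, since replicate 2, which lacks the peaks, had 1.30 times the unique tags. A lower ratio of ChIP to input around the rows was looked for in 82 pairs of matched peaks within 50 kb. Their median log2 fold ratio, replicate 2 over replicate 1, was -0.0265, inside the central 95% of random sets (-0.07 to 0.10). That is the outcome named beforehand as going against this explanation. A lower ratio around some of the rows stays open, since a pooled median can hide it. Only peaks listed in both replicates enter the pairs, so peaks that a lower ratio removed from replicate 2 are left out. The medians by arm differed in sign, but each lay inside its random range. Around the rows on X the median was 0.08 (random sets -0.10 to 0.16), around those on 2L and 3L together -0.10 (-0.11 to 0.12), and around the one on 3R from 25585227, with only 2 such pairs, -0.220 (-0.55 to 0.58), and a difference between the cultures, such as in copy number, was not tested.

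The highest folds were lower in replicate 2, which was the third pattern. Where each position and strand counts once, the fold over the mean background cannot exceed 2 times the effective genome size over the unique tags, which is 18.1 in replicate 1 and 13.9 in replicate 2. No peak exceeded this, and the highest folds stood at 98.7% and 100.02% of it, the latter above 100 only by rounding. Such a ceiling is consistent with 115 of the 119 regions with a fold over 12 in replicate 1 being lower in replicate 2 (medians of 14.08 and 11.77), although regions chosen for a high value in one list tend to be lower in the other anyway.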

How the results depend on the processing

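No paired analysis was possible because no processed file of the inputs was analysed here, and the single group with files has 1 list per replicate number. Of 24 alternative values with a test, 23 kept their direction and their side of the threshold, and of 4 without a test (region counts and summit distance) 3 stayed alike. A further 3, without rows of 5 or more unmatched peaks, are not counted, since that setting cannot lower the overlap or change the shared regions. The number of shared regions moved from 9015 to 4550 when only peaks at or above the median score were kept, since fewer peaks then enter. The lower density on X was no longer past the threshold with replicate 2 alone: leaving out one replicate gave ratios from 0.80 to 0.90, with permutation p-values of 0.00131 without replicate 2 and 0.0651 without replicate 1, and the cause was not tested. Requiring overlap of 50% of both peaks lowered the shared share to 73.4% in replicate 1 and 64.5% in replicate 2, still above the 4.03% and 3.54% of random shifts. Restricted to the 6 arms, the shares were 88.6% and 82.6%, and with only peaks at or above the median score of each list 87.5% and 75.2%. Overlap itself cannot be computed without one of the replicates, and alternatives at start sites were not run. Depth and d differ between the libraries, and their effect on the overlap was not tested.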

Other observations

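Chosen after the values were seen, the sharpest Hsp90 sites by the fold over input in both replicates included 3 on X among the first 5. These were X from 2019417 to 2020100 (684 bp, folds of 17.76 and 13.91), X from 15957416 to 15957965 (550 bp, 17.84 and 13.82) and X from 2034443 to 2035026 (584 bp, 17.27 and 13.91). The other two were on 3R, from 19014623 to 19017682 (3060 bp, 17.84 and 13.36) and from 20374354 to 20375105 (752 bp, 17.35 and 13.73). All 5 stand near the highest fold of their list, so their order says little.

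A hypothesis for the shorter peaks on X is that X is present in fewer copies. This would lower the tags per kb of peak but not the fold over input, if the background of each peak falls with it. The prediction was written before the values were seen, without that condition. The log2 ratio of median folds, X over chromosomes 2 and 3, was 0.0623 in replicate 1 (bootstrap 95% interval 0.01 to 0.10) and 0.00 in replicate 2 (-0.03 to 0.03), so the fold was not lower. Tags per kb of peak were lower on X, 0.93 times in replicate 1 and 0.89 times in replicate 2. The fold does not decide the question: on X it reached 17.84 in replicate 1 and 13.91 in replicate 2, near the ceiling described above. Where the mean background sets the fold, fewer copies would lower the fold as well. The values may reflect copy number, but the size of the drop was not predicted, copy number was not measured here, and peaks of chromosome arms can differ in length for other reasons.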
